A study of Mus musculus with 24 samples.

How the data were processed

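RNA was measured in CD8 and CD4 T cells sorted by flow cytometry from the bone marrow of CByB6F1 mice with immune-mediated bone marrow failure, per the labels. The mice had received no drug, cyclosporine (CSA, a calcineurin inhibitor), low dose ruxolitinib (RUX, a JAK1 and JAK2 inhibitor) or both drugs (RUX+CSA). Each library came from a pool of 2 or 3 mice aged 2 to 5 months, per the labels' protocols, and was made with a SMART-Seq mRNA kit. There were 24 libraries in 8 groups of 3 pools. The CD8 pools are numbered 1 to 12 and the CD4 pools 13 to 24, so CD8 and CD4 libraries were treated as unpaired. Libraries are named here by group and pool number.

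The deposited table holds raw read counts, that is, whole numbers of read pairs per gene with no scaling and no filter, which was checked on the values. Per the file headers, featureCounts 2.0.3 counted the pairs over exons summed by gene in a UCSC annotation, without a strand option, for all libraries in 1 call. Alignment used STAR against mm10, per the submitters' processing notes, and its version is not stated there. The table has 24421 genes by symbol. It holds no mitochondrially encoded genes and, apart from Jchain, none of the antigen receptor or immunoglobulin genes that were searched for, so receptor use was not analysed here. Coordinates are mm10 gene spans from the file.

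From these counts, edgeR 4.0.16 in R 4.3.3 gave trimmed mean of M values (TMM) factors, removed low-count genes with filterByExpr, and tested each gene with a robust quasi-likelihood F test on group means. The 12 libraries of a cell type were fitted together, with 12684 genes tested in CD8 and 13175 in CD4. The 2 comparisons across cell types used all 24 libraries and 13476 genes. The biological coefficient of variation was 0.196 in CD8, 0.279 in CD4 and 0.24 over all libraries, and TMM factors lay between 0.929 and 1.05. Adjusted p-values are Benjamini-Hochberg values over the genes tested, two-sided, with a threshold of 0.05, and come from edgeR unless another tool is named. Log2 fold changes are fitted values with the standard error taken from the F statistic. Levels of named genes are CPM (counts per mega read pairs) of TMM-scaled totals, and levels of marker genes are CPM of all counted read pairs, both as mean ± SD over 3 pools.

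The 16 comparisons were the 3 treatments against untreated, the 3 pairs of treatments and the RUX by CSA interaction within each cell type, CD8 against CD4 without treatment, and the difference of the RUX+CSA effect between the cell types. The comparisons, tests, gene lists, naming rule and alternatives were fixed before the data were examined. For the 6 comparisons with untreated, the named genes were, first, the 8 highest and 8 lowest by log2 fold change among genes past the threshold with a mean log2 CPM of at least 3 and with the 3 libraries of one group all above or all below those of the other, leaving out unnamed models and receptor segments. Next came up to 3 members past the threshold from each functional list, those with the smallest p. Ifng, Irf1, Socs1, Cish, Fasl, Gzmb, Prf1, Il2ra, Mki67, Tbx21 and, in CD4, Foxp3 were always included. Some genes that the rule names are not reported here. Other comparisons took up to 5 genes each way, and where no gene passed, the 3 with the smallest p. List members and marker genes are also named as examples of their lists.

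The 31 lists covered interferon-gamma response, type I interferon response, STAT5 (common gamma chain) targets, calcineurin and NFAT targets, cytotoxic effector, naive and memory, inhibitory receptor and exhaustion, S phase, mitosis, oxidative phosphorylation, glycolysis and hypoxia, MYC and ribosome biogenesis, cholesterol synthesis, NF-kappa-B targets, immediate early and stress, apoptosis and death receptor, homing and chemokine, T helper 1, T helper 2, T helper 17, regulatory T cell and T cell identity genes, and markers of B and plasma cells, macrophages and monocytes, neutrophils and granulocytes, erythroid cells, platelets and megakaryocytes, NK cells, gamma-delta T cells, stroma and endothelium, and stem and progenitor cells. Lists with at least 5 tested genes were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, adjusted within a comparison over 29 lists in CD8 and 30 in CD4. The gamma-delta T cell list had 2 members in the table and was tested nowhere. T helper 17 genes were too few for a test in CD8. Camera asks whether a list ranks above or below the other genes. Its calls were repeated with a correlation estimated from the residuals, and with fry, which asks whether the members move one way on balance.

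Totals ran from 16912085 to 34550183 read pairs per library, and are given elsewhere in units of M (mega). A count of 3, used as the floor, is 0.0868 to 0.177 CPM, and covers counting error only, since read pairs without molecular identifiers are not independent molecules. Pearson's r of log2 CPM across genes lay between 0.974 and 0.996 over the 24 pairs of replicate libraries. The spread between replicates was far above counting error: the chi-square per gene with at least 20 read pairs was 9.92 to 80.1 in these pairs. In simulated counts with 200 changed genes, the CD8 RUX+CSA test over 12517 genes recovered 80% of 2-fold and 98% of 4-fold changes with 6.53% false calls, and the CD4 test over 12982 genes recovered 60% and 84% with 4.55% false calls. The changed genes were drawn only from genes above a minimum mean level, so recovery of changes in low-count genes was not measured. A list shifted in the simulation was called in both and no other list was. The simulated genes were drawn independently of each other, so this does not test list calls where genes move together.

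The alternatives tried were relative log expression factors, no filter on low counts, DESeq2 1.42.0 (Wald test) and limma voom with quality weights. Further ones were the mean of other-cell markers as a covariate and receptor and immunoglobulin genes left out. The remaining ones were leaving out each library in turn, all 24 libraries in the fit, and only the compared groups in the fit. The covariate averaged the markers of B and plasma cells, macrophages and monocytes, neutrophils and granulocytes, erythroid cells, and platelets and megakaryocytes. It left out the NK cell, gamma-delta T cell, stroma and endothelium, and stem and progenitor lists. Added after seeing the data were an exchange of the labels of CD8 CSA 6 and RUX 7, leaving both of these out, and, across cell types, pools paired by their order. Other splits of the libraries into groups of the same sizes were tested as well. No library was left out of the main tests.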

Results

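Gene expression was measured in 12 CD8 and 12 CD4 T cell libraries sorted from the marrow of mice with immune bone marrow failure, a model of aplastic anaemia in which T cells attack the marrow. Each cell type had 3 pools from untreated mice, 3 from mice given CSA, 3 given RUX and 3 given RUX+CSA. Mean depth in CD8 was 21.4 ± 4.14 M read pairs in untreated, 28.1 ± 3.14 in CSA, 22 ± 2.61 in RUX and 29.6 ± 6.35 in RUX+CSA pools (SD, n = 3). In CD4 it was 24.8 ± 6.03, 25.6 ± 4.1, 27.8 ± 6.84 and 24.1 ± 6.66 M in the same order. Between 13240 and 16459 genes had at least 1 read pair in a library. The 10 most abundant genes took 4.34% to 6.18% of a library and ribosomal protein genes 1.33% to 1.79%.

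The sort labels were checked first by comparing CD8 with CD4 cells of untreated mice. Cd8a, a chain of the CD8 coreceptor, stood at 1048 ± 23.9 CPM in CD8 and 4.61 ± 2.85 CPM in CD4 libraries (log2 7.87, SE 0.56, adjusted p = 4.33e-08, n = 3 each). The partner chain Cd8b1 was also higher in CD8 cells (log2 6.24, SE 0.21, adjusted p = 6.04e-15). Cd4 went the other way, with 0.533 ± 0.12 CPM in CD8 and 1334 ± 241 CPM in CD4 libraries (log2 -11.29, SE 0.23, adjusted p = 2.64e-19). Foxp3, the regulatory T cell factor, and Cd40lg, the CD40 ligand of helper cells, were lower in CD8 cells (log2 -4.78 and -5.26, adjusted p = 2.57e-10 and 1.41e-06). Cd244, a receptor of cytotoxic cells, was higher in CD8 cells (log2 5.44, adjusted p = 7.55e-07). Of 13476 genes, 970 were higher and 1354 lower in CD8 cells, 17.2% in all. The total of 2324 was 1506 without CD4 untreated 14. Across all treatments, mean Cd8a stayed between 988 and 1071 CPM in CD8 groups and mean Cd4 between 1346 and 1549 CPM in CD4 groups.

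**Figure D1:**
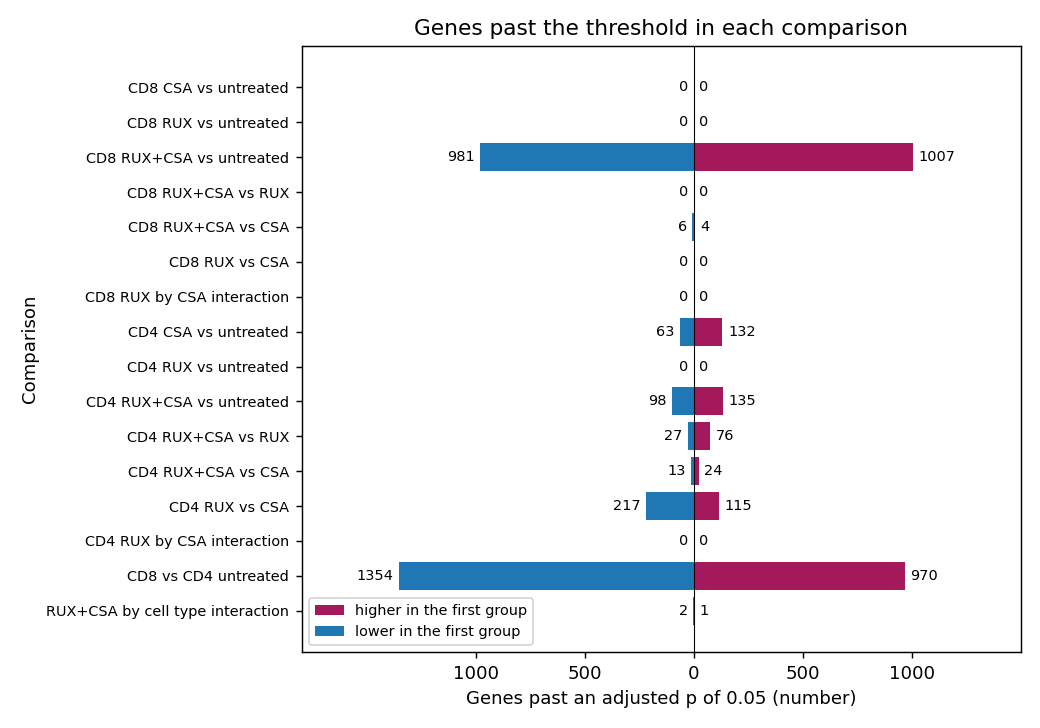
Number of genes past an adjusted p of 0.05 in each of the 16 comparisons, with genes higher in the first group in red and lower in blue. CD8 against CD4 cells (2324 genes) and RUX+CSA against untreated in CD8 cells (1988 genes) stand above all others, the next being 332 genes.

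RUX+CSA was compared with no treatment in CD8 cells to ask what the combination did to the effector cells of the disease. Cxcr5, a chemokine receptor of follicular and memory-like T cells (chromosome 9, 44511787 to 44526421), rose from 11.6 ± 1.45 to 40.9 ± 2.54 CPM (log2 1.82, SE 0.20, adjusted p = 0.00154, n = 3). The inhibitory receptor Btla (chromosome 16, 45224337 to 45252895) rose from 56.7 ± 3.81 to 100.4 ± 5.07 CPM (log2 0.82, SE 0.11, adjusted p = 0.00353). Cd7, a surface protein of T and NK cells (chromosome 11, 121036749 to 121039478), fell from 641 ± 84.8 to 175 ± 8.7 CPM (log2 -1.87, SE 0.24, adjusted p = 0.00353). Cd244 (chromosome 1, 171559193 to 171585316) fell from 92 ± 38.8 to 24.3 ± 2.48 CPM, and the death ligand Tnfsf10 (chromosome 3, 27317077 to 27339665) from 102 ± 23.9 to 43.5 ± 2.8 CPM (adjusted p = 0.00597 and 0.00942). These 5 are among the 17 of the 63 reported genes picked by the naming rule that kept their calls without any 1 library. With the other-cell covariate 1 of the 63 kept its call, and none of these 5 did.

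Some genes of naive and memory T cells were higher with the combination. Of 25 tested members 8 rose and none fell, and 14 rose adjusted over the list alone. Id3, a factor of memory precursors, rose by 1.17 on the log2 scale (SE 0.23, adjusted p = 0.00985). Treml2 went from 1.5 ± 0.17 to 4.45 ± 0.49 CPM (adjusted p = 0.00701), and the memory factor Tcf7 rose by 1.25 (adjusted p = 0.0148). The list passed the camera test (median log2 0.91, adjusted p = 5.39e-06), with adjusted p = 0.458 with an estimated correlation and 0.0277 in fry. Markers of B cells, which share several genes of this list, were higher in the same libraries: mean Cd79a was 0.339 ± 0.37 CPM in untreated and 5.55 ± 5.22 CPM in RUX+CSA pools.

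**Figure D2:**
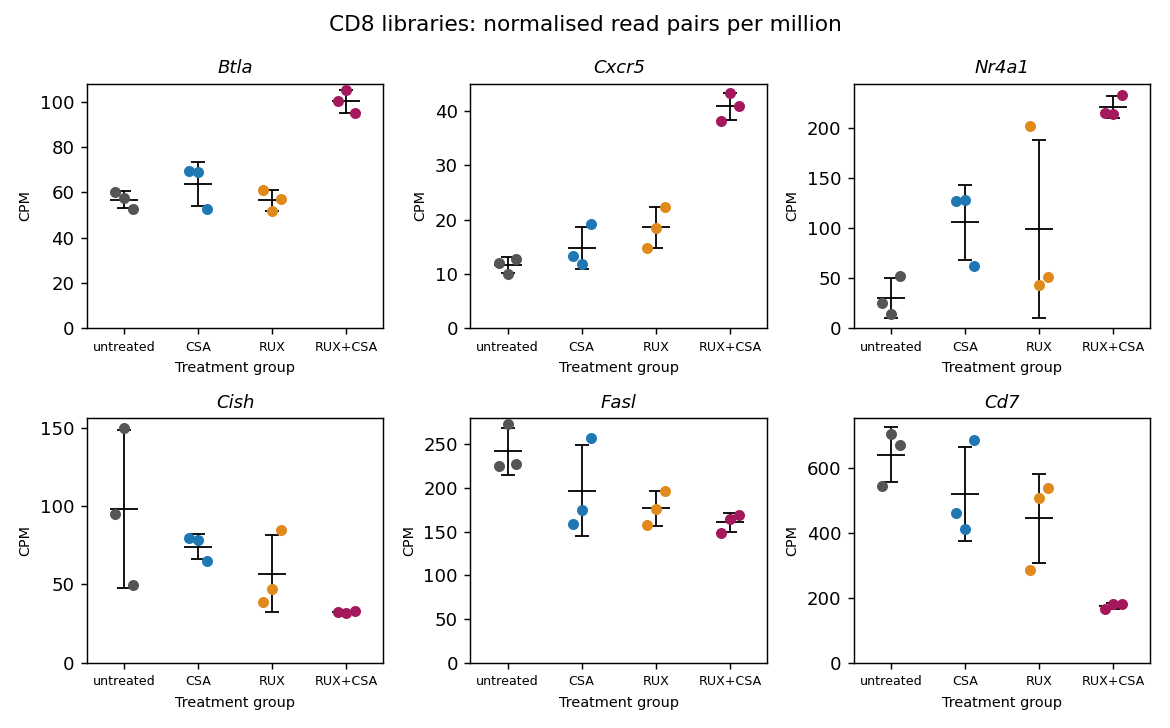
CPM of 6 genes in the 12 CD8 libraries, 1 dot per library, with the group mean as a dash and the SD as a bar (n = 3). Mean Cxcr5 was 11.6 CPM in untreated and 40.9 CPM in RUX+CSA libraries, and mean Cd7 641 and 175 CPM.

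Among cytotoxic effector genes, 6 of 35 rose and 4 fell in RUX+CSA CD8 cells, with the same numbers adjusted over the list alone. Those that rose were Anxa2 (log2 0.90, SE 0.13, adjusted p = 0.00427), Lgals1, Srgn, S100a4, S100a6 and Klrg1. Anxa2, Lgals1, S100a4 and S100a6 encode lipid-, sugar- or calcium-binding proteins common in activated cells rather than killing molecules. Neutrophil markers were higher in the same pools, and with the other-cell covariate the only gene past the threshold was Filip1. RNA of other cells and a change in the T cells are therefore not told apart for these rises. Those that fell were Fgl2, Tnfsf10, Id2 and Fasl. Fasl, the Fas ligand (chromosome 1, 161780692 to 161788495), went from 242 ± 27.3 to 161 ± 11 CPM (log2 -0.59, SE 0.16, adjusted p = 0.0324), but missed the threshold without each of untreated 1, 2 and 3 and RUX+CSA 10, 11 and 12 (adjusted p = 0.0508, 0.118, 0.0534, 0.127, 0.0917 and 0.0526). Gzmb and Prf1, the granule proteins granzyme B and perforin, did not pass (log2 0.65 and -0.21, adjusted p = 0.226 and 0.615). Neither did Ifng (log2 0.025, SE 0.31, adjusted p = 0.964) or Tbx21 (0.24, adjusted p = 0.374). The list as a whole had a median log2 of 0.52 (adjusted p = 0.0177, and adjusted p = 0.551 with an estimated correlation).

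Some targets of the signalling routes that the drugs block moved, but no list of them passed camera. Over all tested genes 15.7% passed the threshold here, a larger share than in each of these lists. Cish, a feedback inhibitor induced by STAT5 (chromosome 9, 107296689 to 107301961), fell from 98.2 ± 50.3 to 32.3 ± 0.46 CPM (log2 -1.60, SE 0.37, adjusted p = 0.0222). That call ended without untreated 2 (adjusted p = 0.0732) and without RUX+CSA 10 or 11 (0.0843 and 0.0717). With the other-cell covariate Cish had neither the call nor the direction (log2 0.23, adjusted p = 0.876). Of 31 STAT5 targets 2 rose and 1 fell, with 0 and 1 adjusted over the list alone (median log2 -0.21, camera adjusted p = 0.568). Of 34 calcineurin and NFAT targets 3 rose and 1 fell, with 4 and 3 adjusted over the list alone. Nr4a1 (chromosome 15, 101266846 to 101274794), a nuclear receptor induced within minutes of receptor signalling, was among those that rose, from 30.3 ± 19.9 to 221 ± 10.8 CPM (log2 2.86, SE 0.67, adjusted p = 0.0239). Egr1 rose from 61.4 ± 21.6 to 185 ± 13.6 CPM (adjusted p = 0.0196). Both calls ended without untreated 1 or 2 and RUX+CSA 10 or 11, with adjusted p between 0.0571 and 0.0798. This list had a median of -0.27 and a mean of -0.12, while camera ranked it upward (adjusted p = 0.898). In the interferon-gamma response list 1 of 39 genes rose and 2 fell, with 0 and 2 adjusted over the list alone (median -0.23, adjusted p = 0.103). Gbp9, a guanylate-binding protein, fell by 0.75 (SE 0.14, adjusted p = 0.0088), whereas Irf1 did not pass (log2 -0.13, adjusted p = 0.554). In the type I interferon list 1 of 43 rose and 4 fell, the same adjusted over the list alone (median -0.09, adjusted p = 0.213).

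Immediate early genes, which cell handling also induces, rose in RUX+CSA CD8 cells in 8 of 24 cases and 9 adjusted over the list alone (median 0.63). Ier2 rose by 0.82 (SE 0.15, adjusted p = 0.00853) and kept its call without any 1 library. The list passed camera (adjusted p = 5.39e-06) and fry (0.0279), with adjusted p = 0.458 with an estimated correlation. Respiratory chain genes had small increases: 11 of 75 rose, 11 adjusted over the list alone, among them Atp5d (log2 0.36, SE 0.083) and Ndufa8 (0.36, SE 0.087). MYC and ribosome biogenesis genes rose in 11 of 42 cases and in 14, with 1 fall, adjusted over the list alone, with medians of 0.21 and 0.23 for these lists. Cholesterol genes rose in 4 and fell in 1 of 26 cases, 8 and 2 adjusted over the list alone. Srebf2, a transcription factor of sterol genes, rose by 0.44 (SE 0.097, adjusted p = 0.016, but 0.0554 and 0.0557 without untreated 2 and RUX+CSA 10). Glycolysis genes rose in 3 of 34 cases, 2 adjusted over the list alone (median 0.16), and homing genes rose in 4 and fell in 1 of 25 cases, 5 and 1 adjusted over the list alone (median 0.38). Cxcr6, a tissue homing receptor, was among the latter, with 1508 ± 165 CPM in untreated and 810 ± 33.2 CPM in RUX+CSA libraries (adjusted p = 0.0219, but 0.0823, 0.0921 and 0.0684 without untreated 2, RUX+CSA 10 and RUX+CSA 11). These 5 lists passed camera with adjusted p between 1.45e-07 and 0.0187, and adjusted p = 0.551 to 0.61 with an estimated correlation. Glycolysis lost its call without untreated 2 or RUX+CSA 12 (0.0907 and 0.062), and homing without untreated 3 (0.0814).

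Mitosis genes ranked downward in RUX+CSA CD8 cells (54 of 55 below 0, median log2 -0.29, adjusted p = 0.000503, and adjusted p = 0.782 with an estimated correlation). Only Kif20b and Cenpf fell, 0 adjusted over the list alone, and the list missed the threshold without untreated 1 (adjusted p = 0.0625). Mki67, the proliferation marker, did not pass (log2 -0.46, adjusted p = 0.135). No S phase gene of 43 passed in either count (median -0.10, adjusted p = 0.505). Inhibitory receptor genes went both ways, 2 of 24 rising and 4 falling, and 2 and 6 adjusted over the list alone (median -0.43, adjusted p = 0.217). Of 28 NF-kappa-B targets 1 rose and 5 fell in both counts (median -0.07, adjusted p = 0.297), and of 32 apoptosis genes 1 rose and 4 fell in both (adjusted p = 0.744, with a median of 0.048, a mean of -0.033 and an upward rank). T helper 1 genes had 1 rise and 1 fall among 15 (adjusted p = 0.217), T helper 2 genes none among 5 (0.505) and regulatory T cell genes 1 rise, Capg, among 18 (0.744), each the same adjusted over the list alone. Socs1 and Il2ra did not pass (log2 -0.81 and -0.43, adjusted p = 0.118 and 0.355).

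Markers of other marrow cells were also higher in the RUX+CSA CD8 pools. Neutrophil markers had a mean log2 CPM of 1.74 ± 3.79 in untreated and 6.55 ± 0.23 in RUX+CSA libraries, erythroid markers -1.59 ± 1.2 and 2.46 ± 0.79, and B cell markers -0.48 ± 0.3 and 1.39 ± 0.87. By gene, 12 of 15 erythroid, 6 of 19 neutrophil, 7 of 15 B cell and 4 of 8 stem and progenitor markers rose and none fell, and 15, 18, 8 and 6 rose adjusted over the list alone. Their camera adjusted p lay between 4.1e-11 and 0.000477, with adjusted p = 0.458 to 0.551 with an estimated correlation, and between 0.00522 and 0.0442 in fry. Macrophage markers split, with 8 of 28 rising (Cd68 by 1.27, adjusted p = 0.00623) and 5 falling (C1qb by -2.09, adjusted p = 0.0266), 10 and 7 adjusted over the list alone (adjusted p = 0.0726). NK cell markers had 1 rise and 1 fall among 10, or 2 and 1 adjusted over the list alone (adjusted p = 0.213), stroma markers 2 falls among 8 in both counts (0.213) and platelet markers none among 6 in either (0.987). Prss34, a basophil protease, went from 0.13 ± 0.23 to 28.1 ± 10.8 CPM (adjusted p = 0.0124, and 0.0508 without untreated 2; log2 -0.41 with the other-cell covariate), and Itgam, an integrin of myeloid cells, from 22.9 ± 16.8 to 137 ± 18.5 CPM (adjusted p = 0.00815). T cell identity genes were close to level in mean log2 CPM, 8.11 ± 0.11 and 8.21 ± 0.015, while 4 of 18 rose, 5 adjusted over the list alone (camera adjusted p = 0.0164, and adjusted p = 0.458 with an estimated correlation; 0.0603 without untreated 3).

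In all, 1007 genes were higher and 981 lower in RUX+CSA than in untreated CD8 cells, 15.7% of those tested, and 685 of them by more than 2-fold. The count was 1303, 538 and 1205 without untreated 1, 2 and 3, and 426 and 656 without RUX+CSA 10 and 11. It was 4311 with voom. In alternatives chosen after seeing the data it was 3521 with the labels of CSA 6 and RUX 7 exchanged and 3893 with these 2 libraries left out, with 1980 and 1986 of the first 1988 among them. With the other-cell marker mean as a covariate 1 gene passed, Filip1, and the marker mean itself lay mostly between the groups (76.6% of its variance), so the drug effect and the other-cell markers overlap in these libraries.

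**Figure D3:**
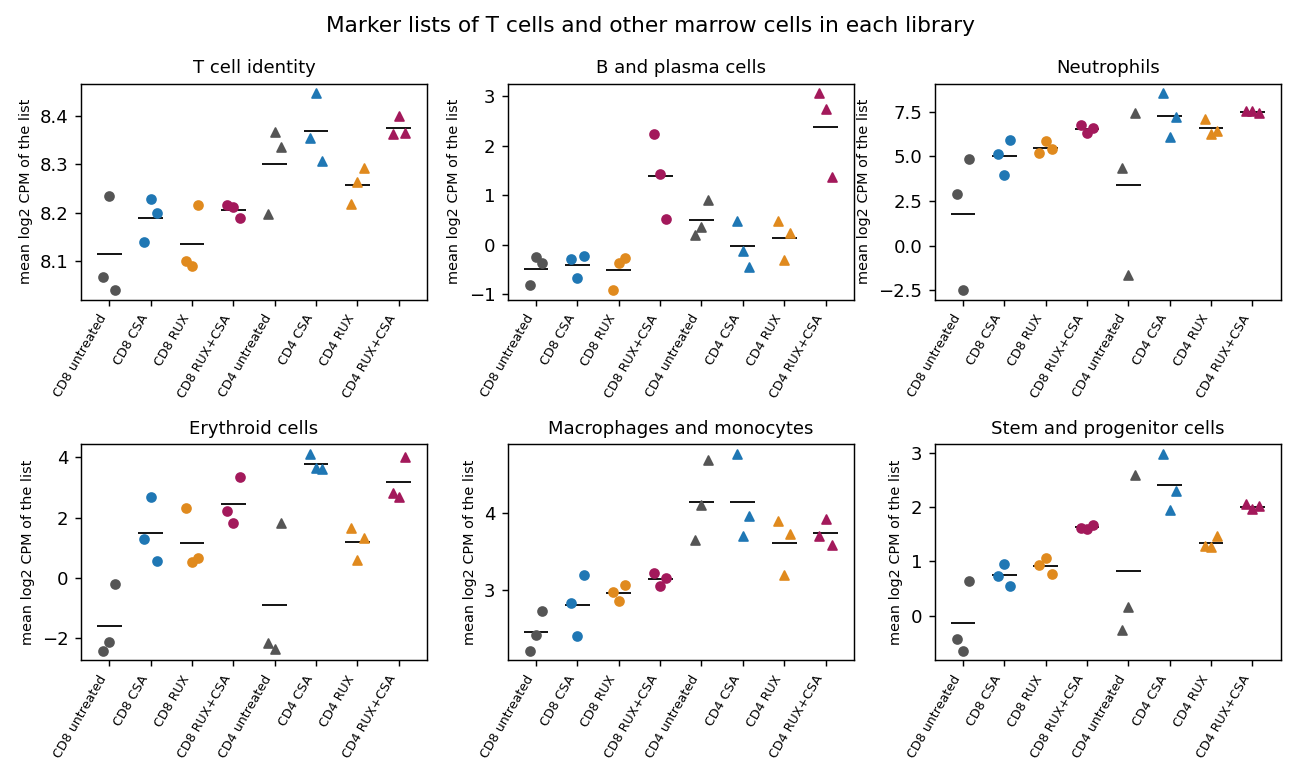
Mean log2 CPM of marker lists in each library, with circles for CD8, triangles for CD4 and a line for the group mean. T cell identity means stay between 8.11 and 8.38 in all 8 groups, while neutrophil means in CD8 libraries go from 1.74 in untreated to 6.55 in RUX+CSA.

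CSA alone was compared with no treatment in CD8 cells to isolate the calcineurin inhibitor. Treml2 stood at log2 1.69 above untreated (SE 0.27, adjusted p = 0.22) and Gzmb at 0.97 (SE 0.36, adjusted p = 0.466), so neither passed. The smallest adjusted p was 0.119, for Gadd45a, a DNA damage and stress gene (log2 1.62, SE 0.22), followed by Treml2 and Cpt1a (log2 -0.45, SE 0.075, adjusted p = 0.22). Ifng, Cish and Fasl did not pass either (log2 0.12, -0.41 and -0.29, adjusted p = 0.918, 0.732 and 0.557). No gene passed in edgeR, with 1233 at an unadjusted p below 0.05. DESeq2 called 72 and voom 321, and edgeR called 1 without untreated 3. The CD8 libraries of the single drugs did not group by label: Klrc1 was 1109 and 1326 CPM in CSA 4 and CSA 5 and 1220 CPM in RUX 7, against 344.5 CPM in CSA 6 and 358.2 and 364.1 CPM in RUX 8 and RUX 9. Mean log2 CPM parted alike for NK cell markers (2.10, 2.33 and 2.15 against 0.74, 0.36 and 0.48) and erythroid markers (1.29, 2.67 and 2.31 against 0.56, 0.54 and 0.65). With the labels of CSA 6 and RUX 7 exchanged 1252 genes passed for CSA, and 616 with both libraries left out. The sources used here do not say whether a sorting day, a batch or a label lies behind this grouping. Of 29 lists 12 ranked upward, among them naive and memory (median 0.57, 3 genes adjusted over the list alone, adjusted p = 1.34e-05), cytotoxic effector (0.41, 1 gene, 0.000112), respiratory chain (0.19, none, 9.58e-12) and erythroid markers (3.59, 14 genes, 1.64e-16). All 12 lost their calls, with adjusted p = 0.408 to 0.625 with an estimated correlation, and no list passed in fry. Other-cell markers were above untreated here too, with neutrophil means of 5.01 ± 0.99 against 1.74 ± 3.79.

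RUX alone was compared with no treatment in CD8 cells to isolate JAK inhibition at this dose. Ifitm2, an interferon-induced membrane protein, stood at log2 1.48 above untreated (SE 0.22, adjusted p = 0.112), Gadd45a at 1.68 (SE 0.22, adjusted p = 0.088) and Cyp4f18 at 3.13 (SE 0.53, adjusted p = 0.324). Cish was at -0.79 (SE 0.37, adjusted p = 0.845) and Fasl at -0.45 (adjusted p = 0.733). None of these passed, nor did any other gene in edgeR, although 744 had an unadjusted p below 0.05. DESeq2 called 83, voom 0, and edgeR called 9 without untreated 3. With the labels of CSA 6 and RUX 7 exchanged 6 genes passed, Ifitm2 and Gadd45a among them (adjusted p = 0.0247 each), and none with both libraries left out (smallest adjusted p 0.0898). Naive and memory genes had 9 members higher adjusted over the list alone and ranked upward (median 0.65, adjusted p = 4.49e-09), with adjusted p = 0.344 with an estimated correlation. Type I interferon genes (median -0.10, adjusted p = 0.00116), inhibitory receptor genes (-0.20, 0.00864) and mitosis genes (-0.18, 1.06e-06) ranked downward with no member past the threshold in either count, with adjusted p = 0.843 with an estimated correlation. Leaving out RUX 7 ended these 3 calls (0.732, 0.93 and 0.606), and so did the exchanged labels. Leaving out untreated 3 ended that of inhibitory receptors (0.397) and untreated 1 that of mitosis (0.0591). Of the 12 lists called, none passed with an estimated correlation or in fry. Neutrophil markers averaged 5.47 ± 0.36 against 1.74 ± 3.79 in untreated.

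The combination was set against each single drug in CD8 cells to see what the second drug added. Against CSA, Cxcr5 was higher (14.8 ± 3.89 in CSA and 40.9 ± 2.54 CPM in RUX+CSA, log2 1.47, SE 0.19, adjusted p = 0.0364), with Zhx2 (log2 0.75, adjusted p = 0.0364) and Gsn, the actin-severing gelsolin (0.64, adjusted p = 0.0388). The calcium channel gene Ryr1 was lower (log2 -1.45, SE 0.18, adjusted p = 0.0364), as were Cd7, Fgl2 and Eif4e3 (log2 -1.57, -1.29 and -0.62, adjusted p = 0.05 when rounded). In all 4 genes were higher and 6 lower, against 10 and 9 with all 24 libraries in the fit and 141 and 124 in DESeq2. The count was 5 without CSA 6, when Cxcr5, Gsn, Ryr1 and Fgl2 still passed, and 0 without CSA 4, CSA 5, RUX+CSA 10, 11 or 12. It was 312 with the labels of CSA 6 and RUX 7 exchanged and 110 with both left out. Interferon-gamma response genes ranked downward against CSA with 0 calls in either count (37 of 39 below 0, median -0.28, adjusted p = 1.52e-05), with adjusted p = 0.737 with an estimated correlation, and lost their call with the exchanged labels. B cell markers ranked upward (median 1.78, 8 genes adjusted over the list alone, adjusted p = 1.06e-07), also with 0.737. Against RUX no gene passed in edgeR. Btla (log2 0.83, SE 0.11), Ryr1 (-1.29, SE 0.18) and Acot11 (-1.13, SE 0.16) had the smallest adjusted p, 0.0523 each, and 2198 genes had an unadjusted p below 0.05. DESeq2 called 484, voom 2929, and edgeR called 255 without RUX 7, 1913 with the exchanged labels and 1481 with CSA 6 and RUX 7 left out. Of the lists 15 were called against CSA and 12 against RUX, and all lost their calls with an estimated correlation (adjusted p = 0.737 to 0.81 and 0.759 to 0.895). Against RUX the number of lists was 7 without RUX 9 and 6 without RUX+CSA 12.

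Between the single drugs in CD8 cells no gene passed in edgeR (230 at an unadjusted p below 0.05; DESeq2 0, voom 179). With the labels of CSA 6 and RUX 7 exchanged 1719 genes differed, and 457 with both left out, so this count of 0 rests on the labels of these 2 libraries. The smallest p belonged to Elmo2 (log2 -0.27), the memory marker Slamf6 (0.43) and Rrp1b (-0.31), each with adjusted p = 1. The RUX by CSA interaction, which asks whether the combination departs from the sum of the log2 effects, had no gene past the threshold either (368 at an unadjusted p below 0.05; DESeq2 1, voom 0). Srpk3 (log2 4.38), the chemokine Ccl1 (-3.23) and Tspan9 (-3.88) had the smallest p, with adjusted p = 0.999. Without RUX 7 the interaction had 2 genes, and it had 0 with the exchanged labels and with both libraries left out (smallest adjusted p 0.474 and 0.0637). The larger number of calls with the combination than with each drug is therefore not shown to exceed the sum of the single effects.

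CSA was compared with no treatment in CD4 cells, where single genes did pass. Klrc1, the NK receptor NKG2A (chromosome 6, 129666016 to 129678973), rose from 57 ± 2.2 to 378 ± 120 CPM (log2 2.73, SE 0.32, adjusted p = 0.00436, n = 3). Klrk1, the activating receptor NKG2D (chromosome 6, 129610323 to 129623864), rose from 45.7 ± 10.5 to 161 ± 14.7 CPM (adjusted p = 0.0012), and Klrd1, the CD94 chain that pairs with NKG2A, from 82.9 ± 21.3 to 192 ± 6.71 CPM (adjusted p = 0.00234). The chemokine Ccl5 (chromosome 11, 83525779 to 83530518) rose from 577 ± 57.6 to 1497 ± 324 CPM (log2 1.38, SE 0.13, adjusted p = 0.000247). Bach2, a repressor that keeps T cells from terminal differentiation (chromosome 4, 32417435 to 32586108), rose from 6.09 ± 1.99 to 24.6 ± 5.65 CPM (log2 2.02, SE 0.27, adjusted p = 0.00213). These 5 genes are among the 12 of the 32 reported genes of the rule that kept their calls without any 1 library. With the other-cell covariate, which leaves out the NK cell list, 19 of the 32 kept theirs.

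Of 36 cytotoxic effector genes tested in CSA CD4 cells, 8 rose and none fell, and 13 rose and 2 fell adjusted over the list alone. Gzmb (chromosome 14, 56258858 to 56262260) rose from 190 ± 38 to 513 ± 80.8 CPM (log2 1.43, SE 0.22, adjusted p = 0.0112, and 0.0555 without CSA 18). The list passed camera (median 0.32, adjusted p = 2.08e-06), also with an estimated correlation (adjusted p = 0.0106) and in fry (2.77e-05), and kept its call without any 1 library. T helper 1 genes had 1 rise, Il12rb2, the interleukin-12 receptor chain (log2 1.43, SE 0.16, adjusted p = 0.000599), and 3 adjusted over the list alone (median 0.33, adjusted p = 0.000985, and adjusted p = 0.204 with an estimated correlation; fry 0.00647). NK cell markers rose in 1 of 10 cases, Klra7, and 2 adjusted over the list alone (median 1.09, adjusted p = 0.00147, and adjusted p = 0.103 with an estimated correlation; fry 0.000646). In mean log2 CPM the NK markers stood at 0.72 ± 0.23 against -0.18 ± 0.089 in untreated CD4 libraries. Whether the cytotoxic and NK genes rose in CD4 T cells or through RNA of NK cells in the pools was not tested. The other-cell covariate leaves out the NK cell list and so does not address it. Ifng, Prf1 and Tbx21 were not among the genes past the threshold (Ifng log2 0.23, adjusted p = 0.801; Tbx21 0.28, adjusted p = 0.274).

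Some regulatory T cell genes were lower with CSA in CD4 cells. Foxp3 (chromosome X, 7579676 to 7595243) fell from 72.9 ± 21.8 to 36.6 ± 3.43 CPM (log2 -0.99, SE 0.18, adjusted p = 0.0127, and 0.0636 without CSA 18). Izumo1r, the folate receptor 4 of regulatory and helper cells, fell from 93.3 ± 19.4 to 47.8 ± 4.67 CPM (adjusted p = 0.00752). Of 19 members 1 rose and 4 fell, and 1 and 7 adjusted over the list alone. The list's rank was downward (median -0.28, adjusted p = 0.0102, and adjusted p = 0.495 with an estimated correlation), with 0.0513 and 0.051 without untreated 14 and 15. Other genes that fell were Pkdcc, a secreted tyrosine kinase (26.6 ± 11.2 to 5.01 ± 1.89 CPM, adjusted p = 0.00196), Tprg and Enpp2. Gcg, the glucagon gene (chromosome 2, 62474530 to 62483653), went from 188 ± 15.7 to 15.5 ± 12.6 CPM (log2 -3.58, SE 0.67, adjusted p = 0.045, with 0.0717 to 0.146 without untreated 13, 14 or 15, CSA 17 or CSA 18).

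**Figure D4:**
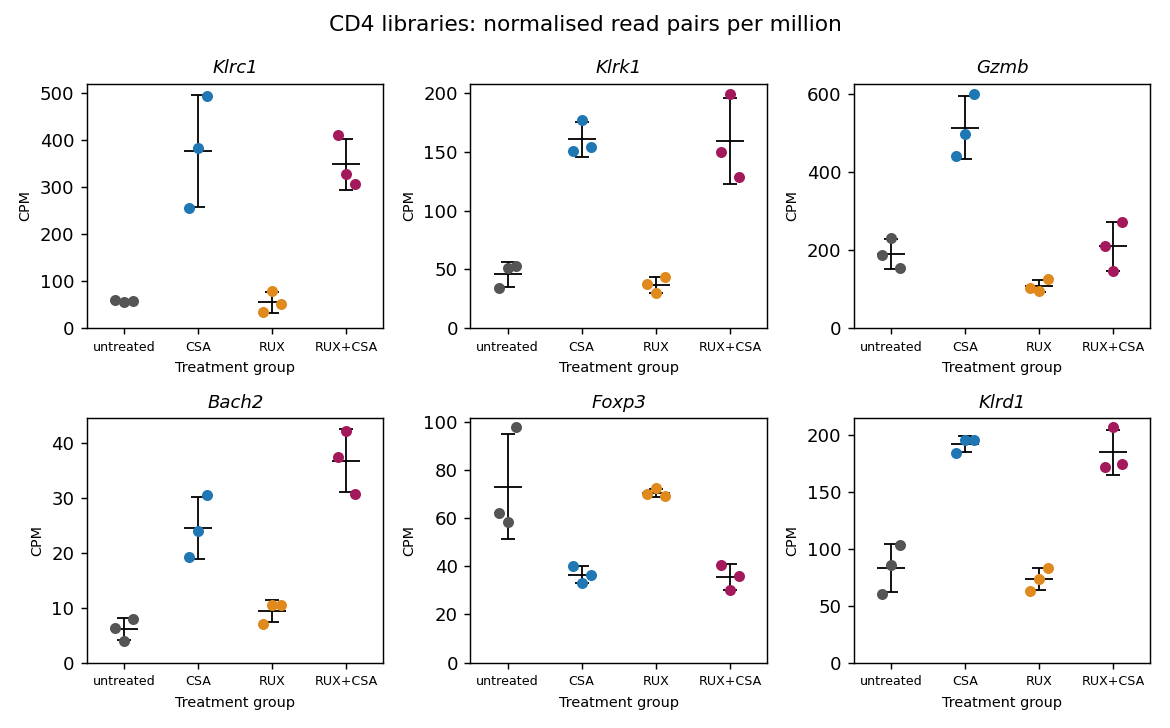
CPM of 6 genes in the 12 CD4 libraries, 1 dot per library, with the group mean as a dash and the SD as a bar (n = 3). Klrc1 averaged 57 CPM in untreated, 378 in CSA, 54.2 in RUX and 349 in RUX+CSA libraries, and Foxp3 72.9 CPM in untreated, 36.6 in CSA and 35.5 in RUX+CSA libraries.

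Cell cycle genes ranked downward with CSA in CD4 cells. All 55 mitosis genes and 42 of 43 S phase genes were below 0 (medians -0.91 and -0.67, adjusted p = 7.04e-18 and 1.82e-12), and 0 and 20 fell adjusted over the list alone, with none over all genes. Both calls ended, with adjusted p = 0.469 with an estimated correlation. Mki67 did not pass (log2 -0.72, SE 0.33, adjusted p = 0.326). Naive and memory genes ranked upward, 3 of 25 rising and 4 adjusted over the list alone (median 0.66, adjusted p = 0.000971, and adjusted p = 0.469 with an estimated correlation). Homing genes had 2 rises and 1 fall among 26, 6 and 3 adjusted over the list alone (median 0.27, adjusted p = 0.0312, and 0.469 with an estimated correlation; 0.0659, 0.211, 0.0611 and 0.0871 without untreated 14, untreated 15, CSA 17 and CSA 18). T helper 2 and T helper 17 genes did not pass as lists (median -0.19 and 0.07, adjusted p = 0.444 and 0.743, with 0 of 9 and 0 of 6 genes past the threshold and 1 and 0 falls adjusted over the list alone), the latter with a mean of -0.025. Calcineurin and NFAT targets were 2 up and 2 down among 37, 4 and 6 adjusted over the list alone (median -0.07, adjusted p = 0.924). Egr3, a target named for that pathway, rose from 14.8 ± 1.35 to 31.4 ± 2.89 CPM (log2 1.09, SE 0.16, adjusted p = 0.00397). Erythroid markers were higher, with means of -0.90 ± 2.36 in untreated and 3.79 ± 0.28 in CSA (3 of 15 rising, 15 adjusted over the list alone), and neutrophil means were 3.37 ± 4.61 and 7.25 ± 1.23. B cell markers ranked downward (median -1.08, or -0.40 with 5 genes set at the floor, adjusted p = 0.0242, and adjusted p = 0.642 with an estimated correlation), with 0.104, 0.0611 and 0.0652 without untreated 15, CSA 17 and CSA 18.

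In total 132 genes rose and 63 fell with CSA in CD4 cells, and 90 differed by more than 2-fold. The total of 195 was 111 without CSA 17 and 48 without CSA 18. DESeq2 called 693 genes and voom 299. With only these 2 groups in the fit there were 13.

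RUX+CSA was compared with no treatment in CD4 cells to follow the combination in the helper population. Klrc1 rose from 57 ± 2.2 to 349 ± 54.8 CPM (log2 2.61, SE 0.32, adjusted p = 0.00556) and Klrk1 from 45.7 ± 10.5 to 159 ± 36.6 CPM (adjusted p = 0.0018). Bach2 rose from 6.09 ± 1.99 to 36.8 ± 5.75 CPM (log2 2.60, SE 0.27, adjusted p = 0.000605), and Bcl6, the master factor of follicular helper cells, from 11 ± 3.23 to 31.3 ± 3.14 CPM (log2 1.52, SE 0.24, adjusted p = 0.00584). Egr1 rose from 92 ± 5.69 to 246 ± 25.1 CPM (adjusted p = 0.00321), and the adhesion receptor Cd44 by 0.73 (SE 0.11, adjusted p = 0.00584). Foxp3 fell to 35.5 ± 5.26 CPM (log2 -1.04, SE 0.18, adjusted p = 0.009). These 7 are among the 12 of 38 named genes that kept their calls without any 1 library. With the other-cell covariate, which leaves out the NK cell list, 17 of the 38 kept theirs. Gzmb, Ifng, Mki67, Tbx21 and Cish did not pass (log2 0.14, 0.58, -1.07, 0.42 and -1.20, adjusted p = 0.811, 0.447, 0.144, 0.0907 and 0.153).

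By list, cytotoxic genes had 7 rises and 1 fall among 36 in RUX+CSA CD4 cells, 12 and 4 adjusted over the list alone (median 0.28, adjusted p = 0.00258, and adjusted p = 0.071 with an estimated correlation; fry 0.000663). NK markers rose in 2 of 10 cases, 4 adjusted over the list alone (median 0.80, adjusted p = 4.78e-05, and adjusted p = 0.0511 with an estimated correlation; fry 9.51e-05). Immediate early genes rose in 5 of 24 cases, 13 adjusted over the list alone (median 0.86, adjusted p = 1.35e-11, and adjusted p = 0.379 with an estimated correlation; fry 0.0267). Nr4a1 was among them (52.7 ± 26.2 to 288 ± 48.7 CPM, adjusted p = 0.0377, with 0.0733 to 0.106 without untreated 13, untreated 14 or any 1 of the RUX+CSA pools 22 to 24). Mitosis and S phase genes ranked downward (medians -0.98 and -0.73, adjusted p = 7.74e-18 and 2.35e-12). Over all genes 1 and 0 of them fell, against 46 and 26 adjusted over the list alone, with adjusted p = 0.397 with an estimated correlation. Naive and memory genes rose in 3 of 25 cases, 6 adjusted over the list alone (median 0.49, adjusted p = 5.9e-05, and 0.397 with an estimated correlation). Regulatory T cell genes had 2 falls among 19, and 2 rises and 6 falls adjusted over the list alone, without a list call (median -0.20, adjusted p = 0.111). Interferon-gamma response genes had 1 fall, Ubd, among 39 and 2 adjusted over the list alone (median -0.10, adjusted p = 0.137). Of 17 lists called here none held with an estimated correlation (adjusted p = 0.0511 to 0.707). RNA of NK cells was not tested as a source of the cytotoxic and NK gene rises here.

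Markers of other cells moved apart in the RUX+CSA CD4 pools. B cell markers rose in 5 of 16 cases, 8 with 3 falls adjusted over the list alone (median 2.22, adjusted p = 5.9e-05, and adjusted p = 0.397 with an estimated correlation; fry 0.0145), and mean Cd79a was 0.715 ± 0.22 CPM in untreated and 11.2 ± 8.63 CPM in RUX+CSA libraries. Erythroid means were -0.90 ± 2.36 and 3.17 ± 0.75. Of the macrophage markers, C1qb, a complement component, fell from 58.7 ± 41.3 to 5.95 ± 3.36 CPM (log2 -3.29, SE 0.66, adjusted p = 0.0456), and the mannose receptor Mrc1 by 3.48 on the log2 scale (SE 0.61, adjusted p = 0.0199). Their calls ended without RUX+CSA 22, 23 or 24 (0.136, 0.0697 and 0.132 for C1qb, and 0.106, 0.0688 and 0.0897 for Mrc1), and that of C1qb without untreated 15 (0.0505). Among 30 macrophage markers 1 rose and 5 fell, 3 and 15 adjusted over the list alone (median -0.58, adjusted p = 0.03, and adjusted p = 0.661 with an estimated correlation; 0.098, 0.258 and 0.0861 without untreated 14, untreated 15 and RUX+CSA 24). The basophil protease Prss34 stood at 0.036 ± 0.062 CPM in untreated and 62.5 ± 22.9 CPM in RUX+CSA libraries (adjusted p = 0.00555), and the related Mcpt8 at 0.483 ± 0.84 and 35.3 ± 8.57 CPM (adjusted p = 0.0464, but 0.066 to 0.121 without untreated 13 or 14 or any 1 RUX+CSA pool).

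In total 135 genes rose and 98 fell, 126 of them by more than 2-fold. This balance turned in other settings, with 270 higher and 399 lower with all 24 libraries in the fit, 417 and 530 in DESeq2, and 127 and 166 without untreated 14. The total of 233 was 58, 92 and 115 without RUX+CSA 22, 23 and 24. DESeq2 called 947 in all, and 88 genes passed with the other-cell covariate.

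RUX alone was compared with no treatment in CD4 cells. No gene passed in edgeR, with 548 at an unadjusted p below 0.05. DESeq2 called 18 and voom 0, and edgeR called 15 without untreated 15. Zeb2, a factor of terminal effector and myeloid cells (log2 -0.92, SE 0.18), the macrophage receptor Csf1r (-2.40, SE 0.44) and Prss34 (0.036 and 13.1 CPM) had the smallest p, with adjusted p = 0.497. Gzmb stood at -0.82 (SE 0.22) and Foxp3 at -0.05, each with adjusted p = 1. Interferon-gamma response genes ranked upward (36 of 39 above 0, median 0.26, adjusted p = 1.04e-06) with no member past the threshold in either count. Macrophage markers ranked downward (median -0.47, 6 falls adjusted over the list alone, adjusted p = 2.1e-06). Neutrophil and erythroid markers ranked upward (medians 0.68 and 1.03, adjusted p = 4.19e-08 and 5.47e-07, none past the threshold in either count), with mean log2 CPM of 3.37 ± 4.61 and -0.90 ± 2.36 in untreated and 6.56 ± 0.45 and 1.19 ± 0.53 in RUX libraries. The calls of these 4 lists held without any 1 library. These and the other 3 lists called had adjusted p = 0.854 with an estimated correlation. The number of lists called was 13 without untreated 14.

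The drugs were then compared with each other in CD4 cells. RUX+CSA stood above RUX in Klrc1 (349 ± 54.8 against 54.2 ± 22.8 CPM, log2 2.69, SE 0.32, adjusted p = 0.00534), in Lmna, which encodes lamin A (log2 3.16, adjusted p = 0.0041), and in Spry2, an inhibitor of receptor kinase signalling (2.61, adjusted p = 0.00466). Pkdcc and Arrdc4 were lower (log2 -1.99 and -1.80, adjusted p = 0.00534 and 0.00466). These 5 kept their calls without any 1 library. Cytotoxic genes had 4 rises among 36, and 16 rises and 3 falls adjusted over the list alone (median 0.37). NK markers had 1 rise among 10 and 6 adjusted over the list alone (median 1.92). Both lists passed camera (adjusted p = 7.31e-07 and 7.75e-08), also with an estimated correlation (0.00496 each), in fry (7.84e-05 and 4.8e-05) and without any 1 library. RNA of NK cells was not tested as a source of these 2 results. Interferon-gamma response genes ranked downward (1 fall, 6 adjusted over the list alone, median -0.37, adjusted p = 1.31e-07, and adjusted p = 0.496 with an estimated correlation), and B cell markers upward (5 rises, 9 adjusted over the list alone, median 2.94, adjusted p = 3.42e-09, and 0.367). In all 76 genes were higher and 27 lower, against 113 and 137 with all 24 libraries in the fit and 295 and 283 in DESeq2. The total of 103 was 35, 43, 46, 41 and 44 without RUX 19, 20 and 21 and RUX+CSA 22 and 23.

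Against CSA, the combination in CD4 cells had higher Sostdc1, a secreted antagonist (15 ± 6.54 in CSA and 129 ± 37.4 CPM in RUX+CSA, log2 3.09, SE 0.36, adjusted p = 0.0107), higher Xcl1, a chemokine for cross-presenting dendritic cells (2.68, adjusted p = 0.0107), and higher Cxcr5 (10.8 ± 3.22 and 37.3 ± 7.38 CPM, adjusted p = 0.0195). Gzmb was lower (513 ± 80.8 in CSA and 209 ± 63 CPM in RUX+CSA, log2 -1.30, SE 0.22, adjusted p = 0.0388), as was Ifngr1, the interferon-gamma receptor chain (1195 ± 121 and 666 ± 63.1 CPM, adjusted p = 0.0138). None of the 10 named genes kept its call in every set of libraries. For Gzmb adjusted p was 0.0536, 0.123 and 0.142 without CSA 16, 17 and 18, and 0.154 and 0.0595 without RUX+CSA 22 and 23. For Ifngr1 it was 0.0512 without CSA 18, and 0.0822 and 0.0586 without RUX+CSA 22 and 23. For Cxcr5, Sostdc1 and Xcl1 it was 0.0543 to 0.0822 without CSA 17, RUX+CSA 22 or RUX+CSA 23, and for Cxcr5 0.0536 without CSA 16. There were 24 genes higher and 13 lower, against 22 and 31 with all 24 libraries in the fit and 110 and 119 in DESeq2. The total of 37 was 17, 6 and 17 without CSA 16, 17 and 18, and 1 without RUX+CSA 22 or 23. Inhibitory receptor genes had 3 rises among 24 (Cd200, Tox and Batf), 4 and 1 fall adjusted over the list alone (median 0.28, adjusted p = 0.000167, and adjusted p = 0.512 with an estimated correlation). B cell markers had 3 rises among 16, 8 adjusted over the list alone (adjusted p = 7.02e-14, and 0.401 with an estimated correlation). The number of lists called was 4, against 8 and 10 without CSA 17 and 18.

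The single drugs differed in CD4 cells in 115 genes higher and 217 lower with RUX than with CSA. Klrc1 was lower with RUX (54.2 ± 22.8 against 378 ± 120 CPM, log2 -2.80, SE 0.32, adjusted p = 0.00256), as were Itga1, an integrin of tissue-resident T cells (-2.81, adjusted p = 0.00161), and Lmna. Pkdcc (41.4 ± 4.27 against 5.01 ± 1.89 CPM, adjusted p = 0.000312), Enpp2 (adjusted p = 0.000363) and Sostdc1 were higher. Each of these 6 kept its call without any 1 library. Gcg was 233 ± 76.5 CPM with RUX and 15.5 ± 12.6 CPM with CSA (adjusted p = 0.0246, but 0.0978, 0.056, 0.0799 and 0.0657 without CSA 17 and RUX 19, 20 and 21). The total of 332 was 191 and 128 without CSA 17 and 18, and 126, 129 and 174 without RUX 19, 20 and 21. The RUX by CSA interaction in CD4 cells had no gene past the threshold in edgeR (629 at an unadjusted p below 0.05; DESeq2 22, voom 0), and 6 without untreated 15. Dpysl2 (log2 0.96, SE 0.16) had the smallest adjusted p, 0.338, and Ccl5 (-0.83, SE 0.19) stood at 0.797.

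CSA and RUX+CSA shared many calls in CD4 cells. Of 132 genes higher with CSA and 135 with RUX+CSA, 63 were shared (1.35 expected if independent), among them Klrc1, Klrk1, Klrd1, Bach2 and Lmna. Of 63 and 98 lower genes 16 were shared (0.469 expected), Foxp3 among them, and none went in opposite directions. Both comparisons use the same 3 untreated pools, which ties their fold changes together. In 20 simulated data sets with no treatment effect and independent genes, the correlation across genes was 0.498 on average, against 0.631 observed. The covariance was 0.135 against 0.479. Shared calls were at most 0, but data without any effect give few calls at all, so this says nothing on the shared calls. For Klrc1 and Lmna, RUX+CSA also stood above RUX, a comparison that shares no library with CSA against untreated. For the other shared calls this was not counted. Controls of 3 pools cannot be divided between the comparisons, and the share of the overlap due to them was not separated.

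The effect of the combination was finally compared between CD8 and CD4 cells. Of 12484 genes tested in both, 55 were higher with RUX+CSA in each cell type (10.8 expected if independent) and 27 lower (7.22 expected), with none opposite. The expectation takes CD8 and CD4 pools as independent, while markers of other cells ran in parallel by pool order. Neutrophil means were 2.86, -2.48 and 4.85 in CD8 untreated 1 to 3 and 4.33, -1.64 and 7.42 in CD4 untreated 13 to 15, and B cell means 2.24, 1.43 and 0.51 in CD8 RUX+CSA 10 to 12 and 3.05, 2.73 and 1.36 in CD4 RUX+CSA 22 to 24. Whether pools of the 2 cell types came from the same mice is not given in the sources used here, and the part of the shared calls due to shared mice was not separated. The interaction, which tests the difference itself, took the pools as unpaired and was past the threshold for 3 genes. Pairing by pool order, chosen after the data were seen, gave a larger count, printed with the processing below. Cd68, a lysosomal protein of macrophages (chromosome 11, 69664213 to 69666170), rose by 1.27 in CD8 cells (SE 0.21, adjusted p = 0.00623) and stood at -0.61 in CD4 cells (SE 0.25, adjusted p = 0.22). Xdh, xanthine dehydrogenase (chromosome 17, 73883895 to 73950196), was at -0.017 in CD8 cells (SE 0.14, adjusted p = 0.943) and rose by 1.00 in CD4 cells (SE 0.11, adjusted p = 0.000605). Each interaction had adjusted p = 0.0464. The count was 0 without CD8 untreated 1, 2 or 3, CD8 RUX+CSA 10 or 11, CD4 untreated 15 or CD4 RUX+CSA 23, and 6, 1 and 5 without CD4 untreated 14 and CD4 RUX+CSA 22 and 24, neither Cd68 nor Xdh among them. Cd68 missed the threshold without any 1 of 11 of the 12 libraries and Xdh without any 1 of 10, with adjusted p up to 0.158. Cd68 kept its call without CD4 untreated 13, and Xdh without that library or CD8 RUX+CSA 12. DESeq2 called 215 genes and voom 35, with 1906 at an unadjusted p below 0.05 in edgeR. RLE factors gave 0 (smallest adjusted p 0.0503) and the other-cell covariate 0 (0.0629). With the labels of CD8 CSA 6 and RUX 7 exchanged the count was 124, and 114 with both left out.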

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

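In this part the tests of the T cell identity list, B cell RNA, the marker covariate and the macrophage markers were chosen only after the results they bear on were seen, and the B cell test was also revised after its first outcome was seen. The division of the splits by mixed labels was chosen after the splits were seen. The depth test and the splits of the samples were set beforehand.

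The difference of the RUX+CSA effect between CD8 and CD4 cells passed its own test for 3 genes, each with adjusted p = 0.0464. This test and the splits below took the pools as unpaired. It was 1.883 on the log2 scale for Cd68 (SE 0.33), -1.006 for Xdh (SE 0.17) and -5.103 for Lgals7 (SE 0.89), a lectin gene outside the naming rule that was chosen after its values were seen. In CD8 cells Lgals7 had 0.172 CPM in untreated and 0.00965 CPM in RUX+CSA libraries, against a floor of 0.0868 to 0.177 CPM, and was not tested there, so -5.103 does not measure the size of a difference. Of 100 drawn splits of these libraries, 10 gave at least 3 genes, the real one included. By the bar of 5 in 100 set beforehand, chance is not excluded for these genes. The highest other gave 834 genes and exchanged all 6 CD8 labels along with CD4 untreated 15 and CD4 RUX+CSA 24. Of the 9 others with at least 3 genes, 7 exchanged all CD8 labels and 2 kept or exchanged all CD4 labels, so that the treatment effect of a whole cell type entered the difference. None of the 84 splits that mixed the labels within both cell types gave 3 genes. Mixing puts treated and untreated libraries in 1 group, which widens the spread and can lower the count. For RUX+CSA against untreated in CD8 cells the real split gave 1988 genes and the highest mixed one 0. The 84 splits therefore do not exclude chance either. The bar also counts splits that carry the treatment effect of a whole cell type, and the share alone does not settle the question.

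The first pattern weighed is the 1988 genes past the threshold with RUX+CSA in CD8 cells. Depth was higher with treatment, but with every CD8 library thinned to the smallest total 1829 genes still passed, 1703 of them among the first set, which argues against depth as the cause. Dilution of T cell RNA by other cells is argued against for the 981 lower genes, whose median log2 was -0.67 (upper quartile -0.47), because the T cell identity list had a median of 0.168 (quartiles -0.012 and 0.36). RNA of other marrow cells and a drug effect cannot be told apart for the whole set: with the marker mean as a covariate 1 gene passed, the median log2 in each gene's first direction went from 0.66 (median SE 0.15) to 0.47 (0.30), and 1878 genes kept their sign. The calls ended through a smaller fold and a larger error together, and 76.6% of the variance of the marker mean lies between these groups.

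The second pattern is the rise of naive and memory genes in the same cells, which RNA of B cells could also bring. Of 8 genes of that list past the threshold, 4 rose by more CPM than the highest Cd79a level of a RUX+CSA library, 11.2 CPM. Among them were Tcf7 (156 CPM), Slamf6 (49.5) and Id3 (11.5). Nsg2 (10.1), Ly6c1 (4.58), Il6ra (4.02) and Treml2 (2.77) rose by less. For the list, these values cannot tell a change in the T cells and B cell RNA apart. The list also ranked upward with CSA alone and RUX alone, calls that ended with an estimated correlation. B cell markers there averaged -0.40 ± 0.24 and -0.52 ± 0.34, against -0.48 ± 0.30 in untreated CD8 libraries. This argues against B cell RNA as the source of the rank with a single drug, and leaves RUX+CSA open. Neutrophil markers averaged 5.01 ± 0.99 with CSA, 5.47 ± 0.36 with RUX and 6.55 ± 0.23 with RUX+CSA, against 1.74 ± 3.79 in untreated CD8 libraries. RNA of neutrophils was not tested as a source of this list's rise, so it stays open with each treatment.

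The third pattern is the shift of other-cell markers in RUX+CSA CD4 pools. A lower share of T cells, with the make-up of the other cells unchanged, would raise the markers of every other cell type alike. The macrophage list had a median log2 of -0.58 (quartiles -1.78 and 0.74) and the erythroid list 3.30 (2.64 and 3.62), which argues against that case only. A lower share together with a changed make-up of the other cells is not excluded by these values. A change in the marrow cells of treated mice also stays open, and neither was tested.

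For comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. The real split of CD8 libraries gave 1988 genes for RUX+CSA against untreated and 10 against CSA, the highest other 0 in both, so 1 of 10 splits reached the real count. It was also 1 of 10 in CD4 cells, with 195 genes for CSA (highest other 15), 233 for RUX+CSA (0), 103 against RUX (0), 37 against CSA (0) and 332 for RUX against CSA (0), and for CD8 against CD4 cells with 2324 (14). Where the real count was 0, 10 of 10 splits reached it: CD8 CSA, CD8 RUX, CD8 RUX+CSA against RUX and CD4 RUX had 0 as the highest other. For CD8 RUX against CSA the highest other was 1719, with CSA 4, CSA 5 and RUX 7 against CSA 6, RUX 8 and RUX 9, which points to a structure of the samples. The RUX by CSA interactions had 0 genes, which 100 of 100 drawn splits in each cell type reach by definition, so these shares say nothing. The highest others were 324 in CD8 and 20 in CD4 cells. The CD8 one counted all 3 untreated libraries as RUX+CSA, so it carries the difference between untreated and treated cells.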

How the results depend on the processing

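In this part the exchange of the labels of CD8 CSA 6 and RUX 7, their leaving out and the pairing of pools were chosen only after the data were seen. With 3 pools a group, calls near the threshold depended on the tool and on single libraries, and depth limits what is seen below the floor of 0.0868 to 0.177 CPM. DESeq2 kept the direction of every reported gene it gave, with the same call in 238 results and a new call in 21. RLE factors kept direction and call in 252 and ended 8 calls. Leaving out receptor genes removed 1 tested gene in each cell type and so tested nothing. Leaving out 1 library kept direction and call in 1096 results for genes and 625 for lists, ended the call in 459 and 124, and reversed 45 and 1. An estimated correlation ended 122 of 125 list calls and fry 104. The direction of a list is its camera rank against the other genes, so a list can reverse while its median log2 keeps its sign. Where a cause is not named below, the cause was not tested.

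Counts of genes differed between settings. With DESeq2 they were, in CD8 cells, 72 for CSA, 83 for RUX, 484 for RUX+CSA against RUX, 265 against CSA and 1 for the interaction. In CD4 cells DESeq2 gave 693 for CSA, 18 for RUX, 947 for RUX+CSA, 578 against RUX, 229 against CSA, 790 for RUX against CSA and 22 for the interaction, and 215 for the difference between cell types. With voom CD8 CSA had 321, RUX+CSA 4311, RUX+CSA against RUX 2929, against CSA 1975 and RUX against CSA 179, CD4 CSA had 299, and the difference between cell types 35. Without a filter CD8 RUX had 2, CD8 RUX+CSA against RUX 10, CD4 RUX+CSA against RUX 206 and against CSA 77, the CD4 interaction 1 and the difference between cell types 7. With the other-cell covariate CD8 RUX+CSA had 1, against CSA 1, CD4 RUX+CSA 88, against RUX 156 and the difference between cell types 0. RLE factors gave 6 for CD8 RUX+CSA against CSA and 0 for the difference between cell types. With all 24 libraries in the fit CD8 RUX had 1, RUX+CSA against RUX 29 and against CSA 19, CD4 RUX+CSA 669 and against RUX 250, and the CD4 interaction 1. With only the compared groups in the fit CD8 RUX+CSA against RUX had 1 and against CSA 16, CD4 CSA 13, RUX+CSA 89, against RUX 560, against CSA 69, CD8 against CD4 cells 1518 and the difference between cell types 42.

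Leaving out 1 library gave, in CD8 cells, 0 to 1 genes for CSA, 0 to 9 for RUX, 426 to 1807 for RUX+CSA, 0 to 255 against RUX, 0 to 5 against CSA, 0 to 0 for RUX against CSA and 0 to 2 for the interaction. In CD4 cells it gave 48 to 204 for CSA, 0 to 15 for RUX, 58 to 293 for RUX+CSA, 35 to 90 against RUX, 1 to 31 against CSA, 126 to 283 for RUX against CSA and 0 to 6 for the interaction. It gave 1506 to 2903 for CD8 against CD4 cells and 0 to 6 for the difference between cell types.

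With the labels of CD8 CSA 6 and RUX 7 exchanged there were, in CD8 cells, 1252 genes for CSA, 6 for RUX, 3521 for RUX+CSA, 1913 against RUX, 312 against CSA and 1719 for RUX against CSA, and 124 for the difference between cell types. With both left out these were 616, 0, 3893, 1481, 110, 457 and 114. The exchange kept direction and call in 103 results for genes and 45 for lists, brought a call in 13 genes, ended it in 16 lists and reversed 9 and 4. Leaving both out kept 106 and 56, brought 12, ended 7 and reversed 7 and 2. Reversed with the exchange were, for CD8 CSA, Ifng -0.176, Irf1 -0.155 and Prf1 -0.016, and for CD8 RUX, Ifng 0.261, Irf1 0.122, Socs1 0.051, Gzmb -0.139, Prf1 0.413, Tbx21 -0.138 and the inhibitory receptor list 0.097. For RUX+CSA against CSA the naive and memory list had a median of -0.115 and S phase 0.038, while the type I interferon list turned in rank only, with -0.069. With both left out CD8 CSA had Irf1 -0.009 and Mki67 0.09, and CD8 RUX had Ifng 0.302, Irf1 0.145, Gzmb -0.233, Prf1 0.113, Tbx21 -0.089 and the type I interferon list 0.027, while the inhibitory receptor list turned in rank only, with a median of -0.003.

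CD8 pools 1 to 12 and CD4 pools 13 to 24 share no number. Paired by order, their deviations from the group means over genes correlated at 0.316, 0.507 and 0.562 in untreated and 0.094, 0.03 and 0.081 in RUX+CSA pools. Within its group 9 of 12 CD8 libraries correlated best with their own partner, and 12 of 12 once CSA 6 and RUX 7 had changed places, a hint from the data and not from the design. With these pairs as a block there were 2757 genes for CD8 against CD4 cells and 69 for the difference between cell types.

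Other reversed values belonged to genes without a call except where the covariate is named. With voom they were, for CD8 CSA, Irf1 -0.042 and Mki67 0.089, and for CD8 RUX, Ifng 0.17, Irf1 0.082, Gzmb -0.126, Prf1 0.104 and Tbx21 -0.064. For CD4 RUX they were Cish 0.025 and Tbx21 0.059, and for CD4 RUX+CSA, Irf1 -0.072. Without a filter Irf1 was -0.01 in CD4 RUX+CSA. With the covariate CD8 CSA had Ifng -0.22, Socs1 0.348, Cish 0.76 and Prf1 -0.198, and CD8 RUX had Cish 0.444 and Il2ra 0.981. CD8 RUX+CSA had Prss34 -0.41, F13a1 -0.488, Retnlg -0.724, Cd24a -0.005, Mmp8 -0.594, Cxcr2 -0.253, Cish 0.232, Eomes -0.019, Ifng -0.556 and Il2ra 1.359. CD4 CSA had Ifng -0.114, Irf1 -0.028 and Cish 0.018, CD4 RUX Tbx21 0.062, and CD4 RUX+CSA Irf1 -0.13.

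Log2 ranges without 1 library that crossed 0 were, for CD8 CSA, Mki67 -0.271 to 0.098, Socs1 -0.365 to 0.074, Cish -0.724 to 0.034, Il2ra -0.272 to 0.496 and Irf1 -0.01 to 0.084. For CD8 RUX they were Il2ra -0.548 to 0.219, Ifng -0.442 to 0.306, Prf1 -0.182 to 0.331, Tbx21 -0.11 to 0.113, Irf1 -0.201 to 0.149, Gzmb -0.23 to 0.446, the type I interferon list -0.253 to 0.031 and the inhibitory receptor list -0.384 to 0.002. For CD8 RUX+CSA they were Ifng -0.092 to 0.275, Il2ra -0.744 to 0.023 and Prf1 -0.379 to 0.135. For CD4 CSA they were Irf1 -0.047 to 0.224, Cish -0.69 to 0.015 and Fasl -0.219 to 0.026. For CD4 RUX they were Socs1 -0.105 to 0.403, Fasl -0.177 to 0.193, Mki67 -0.562 to 0.133, Tbx21 -0.162 to 0.101, Cish -0.578 to 0.127, Prf1 -0.267 to 0.177 and Foxp3 -0.184 to 0.222. For CD4 RUX+CSA they were Irf1 -0.117 to 0.07, Prf1 -0.42 to 0.051, Gzmb -0.098 to 0.334 and the calcineurin and NFAT list -0.07 to 0.228.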

Other observations

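The tests of Y-linked genes and of exchanged labels in this part were chosen only after the values they bear on were seen.

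CD8 libraries of the single drugs fell into sets that did not follow the drug. Gzmb was 1728 and 1684 CPM in CSA 4 and CSA 5 and 1233 CPM in RUX 7, against 716.2 CPM in CSA 6 and 678.6 and 515.7 CPM in RUX 8 and RUX 9. In the same order Klrc1 was 1109, 1326 and 1220 CPM against 344.5, 358.2 and 364.1 CPM. High Gzmb and high Klrc1 thus went together in these 6 libraries. NK cell markers parted the same way, with mean log2 CPM of 2.10, 2.33 and 2.15 against 0.74, 0.36 and 0.48, and so did erythroid markers, with 1.29, 2.67 and 2.31 against 0.56, 0.54 and 0.65. In CD4 cells, where Klrc1 was high with CSA and not with RUX, the RUX minus CSA difference over 13476 genes correlated at 0.146 with that of CD8 cells by the labels. It correlated at 0.487 with CSA 6 and RUX 7 exchanged, the value farthest from 0 among the 10 ways to part these libraries. With each cell type centred on its 6 single-drug libraries, RUX 7 correlated at 0.105 to 0.458 with CD4 CSA and -0.303 to -0.231 with CD4 RUX libraries, and CSA 6 at -0.315 to -0.028 and 0.166 to 0.24. Exchanged labels are a hypothesis consistent with the 0.487, with a partner out of place in each group. A sorting day or batch is not given in the sources used here. It and a difference in RNA of other cells were not tested as causes and stay open. If the labels were exchanged, every value for CSA or RUX alone in CD8 cells would change, and the tests kept the labels as given.

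Neutrophil markers were lowest in CD8 untreated 2 and CD4 untreated 14, with a mean log2 CPM of -2.48 and -1.64. Without CD8 untreated 2 RUX+CSA had 538 genes past the threshold in CD8 cells, and without CD4 untreated 14 it had 293 in CD4 cells. The 2 gamma-delta T cell markers in the table averaged -2.78 ± 0.45 in untreated and -1.16 ± 0.97 in RUX+CSA CD8 libraries, and -2.33 ± 1.13 and -0.033 ± 0.83 in CD4 libraries. Gcg differed between cell types without treatment, with 3.66 ± 1.97 CPM in CD8 and 184 ± 15.4 CPM in CD4 libraries (adjusted p = 0.000979).

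The labels give female mice, while Y-linked genes were read in all 24 libraries. The lowest level of Ddx3y, Eif2s3y, Uty and Kdm5d in any library was 26.5 CPM, and the highest level of Xist, the transcript of the silenced X chromosome, was 0.439 CPM. Were the cells female and these reads from X-linked paralogs, Xist would be high, so its level argues against that. Male origin of the sorted T cells is a hypothesis consistent with the 26.5 CPM, and the sex of the cell donors is not given in the sources used here.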
